A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

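The study measured messenger RNA of Escherichia coli K-12 MG1655, the standard laboratory strain, with 8 Agilent two-colour oligonucleotide arrays. Per the labels' protocols, cells grew in 40 mL of M9 minimal medium with 0.4% glucose in 250 mL flasks at 37 °C and 90 rpm in the dark. At an OD600 of 0.5 to 0.6 the cultures received 2 mM sodium metabisulfite, which corresponds to 4 mM bisulfite. RNA was taken before and after this addition, and 5 µg was labelled. No untreated culture sampled at the later time is named in the sources used here. If untreated RNA is the RNA taken before the addition, an effect of sulfite cannot be told apart from elapsed time and further growth. Words such as "after sulfite" below carry this limit. The length of the exposure is not given in the sources used here. The labels place sulfite RNA in the Cy3 channel and untreated RNA in the Cy5 channel of 6 arrays (sulfite 1 to 6), and untreated RNA in both channels of the other 2 arrays (untreated 1 and 2). No array carried the opposite dye orientation. The labels do not say that the arrays of a group came from separate cultures, so n counts arrays and the p-values measure the spread between these arrays, which may be technical.

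Per the file headers, the authors extracted the spots with Agilent Feature Extraction 10.7.3.1. The scanner files hold the intensity of each spot and of its local background in both channels, without normalization, as deposited. They also hold processed intensities, per the file headers corrected for background and for dye by a linear and a lowess step, and a log10 ratio of Cy5 over Cy3 made from these. Spot flags for signal well above background, saturation and outlier pixels are in the same deposited files. The submitters' processing notes also name limma, without a version or a role. The authors' deposited series table holds log2 values. On each of the 8 arrays it matched the scanner's log ratio after conversion to log2 and averaging over the spots of a probe (slope 0.999 to 1.002 and r of 0.998 to 1.00 across probes), so its scale and its direction, Cy5 over Cy3, are known and no further centring was found. Its column medians were -0.08, -0.03, -0.06, -1.25, -1.04 and -1.12 for sulfite 1 to 6, and -0.09 and -0.08 for untreated 1 and 2. The deposited table gives values for 830 of 9197 probes, chosen by a filter that is not stated in the sources used here. Of these probes, 98.7% had an absolute mean log2 ratio over 1 on sulfite 4 to 6 and 18.9% had one on sulfite 1 to 3.

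The values used here were computed from the mean and background intensities. Background was corrected with normexp at an offset of 50 over all 15683 spots, and each array was normalized by loess with weight 0 for the 4250 control spots and for outlier spots, in limma 3.58.1 and R 4.3.3. Outlier spots were then set to missing, spots of a probe were averaged, and probes of a gene were averaged. Of the 4210 K-12 loci on the array, 24 had more than 1 probe. The ratio is written as log2 of Cy5 over Cy3 throughout. K-12 probes carry locus tags, and 4053 of the 4210 were named through the locus tags of the RefSeq annotation of assembly ASM584v2; the others kept the name in the array files. Probe positions are those of the array design, whose genome build is not given in the sources used here. A probe was kept where its Cy3 signal was well above background on at least 2 of the 8 arrays, which left 3869 genes. No K-12 spot was saturated. Every gene named by the rule below was well above background in Cy3 on all sulfite arrays and in Cy5 on at least 3 of them. Probes for other E. coli strains and custom probes stayed out of the tests of K-12 genes.

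The 6 sulfite arrays were compared with the 2 untreated arrays by limma's linear model and empirical Bayes test, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. The ratio of the untreated arrays was tested against 0 in the same model. Before the data were examined, 37 gene lists were fixed, with 637 entries, of which 602 were measured. For sulfur and redox they were cysteine synthesis and sulfate assimilation, taurine and sulfonate use, methionine synthesis, methionine sulfoxide repair, sulfane sulfur and sulfide handling, molybdenum cofactor synthesis, OxyR, SoxRS, and thiol and glutathione redox. For metals they were Isc assembly, Suf assembly, iron acquisition, and copper and zinc homeostasis. For stress they were RpoS general stress, acid resistance, heat shock, envelope stress (SigmaE and Cpx), phage shock, SOS, the electrophile and chlorine response, multidrug efflux (Mar), and osmoprotection and potassium uptake. For growth and energy they were ribosomal proteins, ribosome hibernation, ATP synthase, aerobic respiration, anaerobic respiration and fermentation, the tricarboxylic acid cycle, glycolysis and glucose uptake, and the pentose phosphate pathway. The rest were arginine, branched-chain, histidine and aromatic amino acid synthesis, purine and pyrimidine synthesis, flagella and chemotaxis, and curli and biofilm. The lists were tested with camera at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry served as alternatives, and 353 missing values were filled with the mean of the group for these set tests. For each list the number of called members is given over all genes and adjusted over the list alone. Also fixed before the data were examined was the rule for named genes. It takes the 12 largest changes in each direction among called genes whose 6 sulfite arrays all lay on the same side of both untreated arrays. It adds, for each list with a camera call or at least 3 called members, up to 4 called members with the smallest adjusted p. It always includes cysB, cysD, cysI, cysJ, cysK, tauA, metE, katG, soxS, recA, ibpA, fliC, rpoS and gapA. This gave 35 genes.

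All 8 arrays lay on 1 slide. Sulfite 1 to 3 and untreated 1 occupied slide column 1, and sulfite 4 to 6 and untreated 2 occupied slide column 2, so each column holds both groups. Results are therefore also given with the column as a block and within each column, the latter from a model of the 4 combinations of group and column with a pooled spread. Within a column the lone untreated array is assumed to vary like the other arrays. Both untreated arrays lay in row 4 of the slide, which held no sulfite array, so slide row and group cannot be told apart. The alternatives fixed beforehand changed the background correction, the normalization, the filter, the control, the blocks, the arrays, the variance model, the probe rule, the threshold or the source of the values. The models within slide columns were added after seeing the data.

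The fit was tested on simulated data with the observed variances and 50 changed genes at each of 4 sizes among 3869. For the comparison of sulfite with untreated arrays it recovered 16%, 56%, 94% and 98% of genes changed by 1, 2, 4 and 6 on the log2 scale, with 4 false calls among 136. For the difference between slide columns, simulated over 3861 genes, the shares were 0%, 6%, 86% and 92%, with 12 false calls among 104, and within column 2 there were 11 false calls among 140. In these runs the models with slide columns made more false calls than the threshold of 0.05 stands for. Each run was a single simulated data set, and none is given for column 1, so their rate of false calls is not known. Calls from these models may hold more false ones than the threshold stands for. Camera, run with 37 lists, called a simulated shift of 1 in the list of flagella and chemotaxis genes and no other list. Only that list was shifted, so the run does not measure how often camera makes false calls on the real lists. The number of arrays limits the precision of all values.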

Results

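The data are 8 two-colour arrays of E. coli K-12 MG1655 messenger RNA, 6 labelled as sulfite-treated against untreated RNA and 2 with untreated RNA in both channels. The study asks how the cells adapted to a concentration of bisulfite that did not kill them. Bisulfite and sulfite are the forms in which metabisulfite exists in water, and sulfite is also the compound that the cell reduces to sulfide on the way to cysteine. The median spot intensity of K-12 probes ranged from 227 to 375 in Cy3 and from 197 to 282 in Cy5, over median local backgrounds of 19 to 20 and 66 to 70. Between 74.0% and 92.0% of K-12 spots were well above background in Cy3, and between 64.4% and 84.6% in Cy5. The SD of the log2 ratio over genes was 1.02 to 1.23 on the sulfite arrays, and 0.48 and 0.66 on the untreated arrays.

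The direction of the sulfite effect is not settled by these files. The labels assign Cy3 to sulfite RNA and Cy5 to untreated RNA on the sulfite arrays, but across genes it was the Cy3 channel that resembled untreated RNA. The Cy3 channels of the 6 sulfite arrays had a mean r of 0.96 with the Cy5 channels of the untreated arrays, whereas their own Cy5 channels had a mean r of 0.85. Cy3 was the closer channel on 6 of 6 arrays. This comparison was chosen after the values were seen, and all 6 arrays are set against the same 2 untreated channels, so no p-value is given. Genes are not independent replicates, so each r only describes likeness. Ratios are therefore given as log2 of Cy5 over Cy3, and "lower in Cy5" means lower on the sulfite arrays relative to the untreated arrays. By the labels, a gene lower in Cy5 was higher after sulfite; with the channels exchanged, it was lower after sulfite. Sizes, p-values and counts are the same under both readings. The log2 ratio of sulfite 1 correlated with that of untreated 2 at r = -0.41 across K-12 genes, and at r = -0.19 over all probes in the scanner's own log ratio. The other r between a sulfite and an untreated array ran from -0.05 to 0.52 across K-12 genes.

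**Figure D1:**
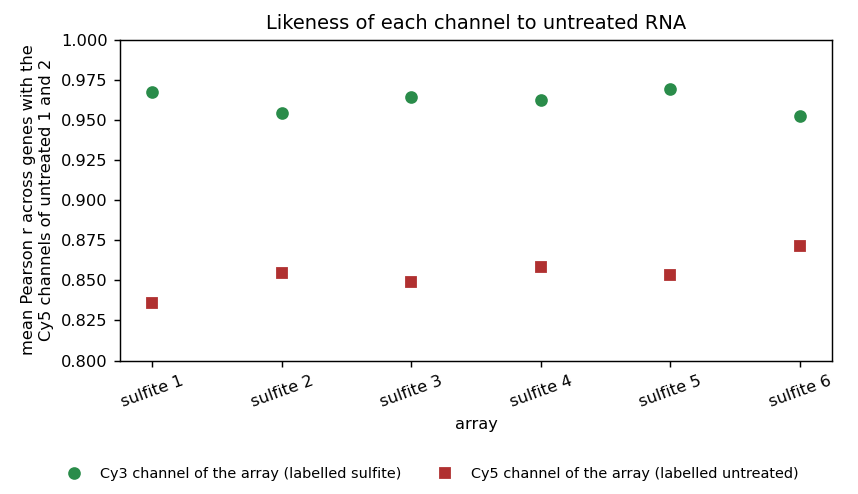
Mean Pearson r across genes (vertical axis, no unit) between each channel of the 6 sulfite arrays (horizontal axis) and the Cy5 channels of untreated 1 and 2; circles are Cy3, squares are Cy5, and the axis starts at 0.80. The Cy3 points lie between 0.952 and 0.969 and the Cy5 points between 0.836 and 0.872.

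On the sulfite arrays, some genes for making pyrimidines, branched-chain amino acids and cysteine, single genes of glutamate synthesis and genes of copper export were far lower in Cy5 than in Cy3, while most members of these gene lists did not pass the test. pyrB and pyrI, the catalytic and regulatory chains of aspartate transcarbamoylase, which opens pyrimidine synthesis, were 39.8-fold and 37.9-fold lower in Cy5. ilvC, an enzyme common to isoleucine and valine synthesis, was 35.1-fold lower, and cusB and cusF of the copper and silver efflux system were 27.2-fold and 23.0-fold lower. In all, 34 genes were lower in Cy5 and 1 gene, fdoI, was higher in Cy5 (limma, adjusted p under 0.05, 3869 genes tested). All 34 lay below both untreated arrays on every sulfite array that measured them. By the labels these 34 genes were higher and fdoI lower after sulfite; with the channels exchanged, the 34 were lower and fdoI higher after sulfite.

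These counts rested on both untreated arrays. The number of genes lower in Cy5 was 4 without untreated 1, 4 without untreated 2 and 21 without sulfite 5, and fdoI was no longer called without untreated 1, untreated 2, sulfite 1, sulfite 2, sulfite 3 or sulfite 6. With the slide column as a block, 50 genes were lower and 3 higher in Cy5. Within column 1, 67 were lower and 18 higher, and within column 2, 27 were lower and 14 higher. Of these, 17 genes were lower and 1 was higher in both columns, against 0.469 and 0.0653 for independent lists, but both column tests use the same pooled spread of a gene. In 100 simulations without change, 0 genes were called in both columns, but adjusted tests make few calls at all in such data. The column 2 differences were also shuffled over the genes 100 times, each gene keeping its spread. The mean was then 3.53 lower and 0.58 higher in both columns, and the highest 8 and 3. Shuffling gave a mean of 304.25 calls in column 2, far more than the 27 lower and 14 higher above. The shuffled data are thus unlike the real data, and neither run measures the overlap that chance would give.

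The pyrimidine genes held the largest ratios. The log2 ratio of pyrB averaged -5.22 ± 0.41 (SD, n = 6) on the sulfite arrays and 0.10 ± 0.06 (SD, n = 2) on the untreated arrays, a difference of -5.31 ± 0.32 (SE, limma adjusted p = 0.000152). Its probe, which the array files assign to locus b4245, lies at positions 4469759 to 4469818 in the array design. pyrI (b4244) differed by -5.24 ± 0.28 (SE). The difference was -5.39 within column 1 and -5.24 within column 2 for pyrB, and -5.32 and -5.16 for pyrI. purL, which acts in purine synthesis, differed by -2.69 ± 0.43 (SE, limma adjusted p = 0.0341). Of 20 measured members of the purine and pyrimidine list, 3 were lower in Cy5 and 17 did not pass the test, and 7 were lower when adjusted over the list alone. codB, the cytosine permease, was 10.8-fold lower (b0336, difference -3.44 ± 0.44, SE).

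Among the amino acid genes, the branched-chain list had 3 of 15 measured members lower in Cy5, and 11 when adjusted over the list alone. ilvC averaged -5.00 ± 0.87 (SD, n = 5, one spot left out as an outlier on sulfite 4) on the sulfite arrays and 0.14 ± 0.51 (SD, n = 2) on the untreated arrays. Its difference was -6.11 within column 1 and -3.85 within column 2. ilvB and ilvA, which act earlier in the same routes, were 8.43-fold and 9.14-fold lower. All 8 members of the histidine list were lower when adjusted over the list alone, and 2 over all genes, hisA (4.85-fold) and hisF (3.82-fold). In the arginine list, 2 of 12 members were lower, and 4 when adjusted over the list alone. They were carB, the large chain of carbamoyl phosphate synthetase, which also feeds pyrimidine synthesis (18.9-fold), and artJ, an arginine-binding transport protein (8.80-fold, well above background in Cy5 on 5 of 6 arrays). Outside the lists, gltD, the small chain of glutamate synthase, was 20.4-fold lower, lysC, an aspartate kinase, 10.4-fold lower, and dppD of the dipeptide transporter 14.1-fold lower.

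In the list of cysteine synthesis and sulfate assimilation, 2 of 18 measured members were lower in Cy5, and 11 when adjusted over the list alone. cysJ, the flavoprotein chain of sulfite reductase, averaged -5.03 ± 0.92 (SD, n = 6) on the sulfite arrays and -0.58 ± 0.14 (SD, n = 2) on the untreated arrays, and was 21.8-fold lower (limma adjusted p = 0.0182). cysD of sulfate adenylyltransferase was 16.4-fold lower (limma adjusted p = 0.0368). cysI, the other chain of sulfite reductase, had a difference of -3.58 ± 0.86 (SE) and did not pass (limma adjusted p = 0.145), but passed without sulfite 3 (-4.09). cysK, a cysteine synthase, had -2.12 ± 0.77 and cysB, the regulator of these genes, -0.70 ± 0.35 (SE), and neither passed.

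The copper and zinc list had 4 of 15 measured members lower in Cy5, and 6 when adjusted over the list alone. cusB averaged -4.10 ± 0.33 (SD, n = 6) on the sulfite arrays and 0.67 ± 0.01 (SD, n = 2) on the untreated arrays (b0574, probe at 596846 to 596905 in the array design). cusA, the pump of the same system, was 4.18-fold lower and above background in Cy5 on 4 of 6 arrays. copA, the copper-exporting ATPase, was 9.15-fold lower, but its untreated ratios were -0.23 and 1.01; the difference was -3.81 without untreated 1 and -2.57 without untreated 2, and neither passed. katE of the RpoS list, a catalase, was 5.99-fold lower and the only one of 23 members called. mdtE of the acid resistance list, a part of a multidrug efflux pump, was 5.04-fold lower, with signal above background in Cy5 on 3 of 6 arrays. It was the only one of 17 members called, and 8 passed when adjusted over the list alone. fdoI, a membrane chain of an aerobic formate dehydrogenase, averaged 2.60 ± 0.67 (SD, n = 6) on the sulfite arrays and -0.28 ± 0.02 (SD, n = 2) on the untreated arrays, a 7.36-fold difference (limma adjusted p = 0.0352).

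The other genes fixed beforehand did not pass. metE, the methionine synthase that works without cobalamin, had a difference of -3.26 ± 0.75 (SE, limma adjusted p = 0.153), with -4.19 within column 1 (adjusted p = 0.0211) and -1.95 within column 2. gapA of glycolysis had -1.91 ± 0.59, the catalase gene katG -1.28 ± 0.44 and tauA of taurine uptake -0.52 ± 0.31 (SE). The tauA difference was -0.82 without untreated 1 and -0.22 without untreated 2. The regulator gene soxS had 0.08 ± 0.47 and recA, central to DNA repair, 0.18 ± 0.45 (SE). For recA only 4 sulfite arrays gave a value, and sulfite 4 alone in column 2. fliC, the flagellin gene, had -1.07 ± 0.81, rpoS -0.66 ± 1.76 and ibpA, a small heat shock protein gene, 0.86 ± 1.48 (SE). The averages of rpoS and soxS join opposite values. Within columns 1 and 2, rpoS differed by -2.46 and 2.11, and soxS by -0.55 and 0.71. Against 0, rpoS was at -1.88 and 2.95 and soxS at -0.60 and 0.63, each with a limma adjusted p under 0.05. Apart from metE, the adjusted p-values of these genes were between 0.302 and 0.999.

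**Figure D2:**
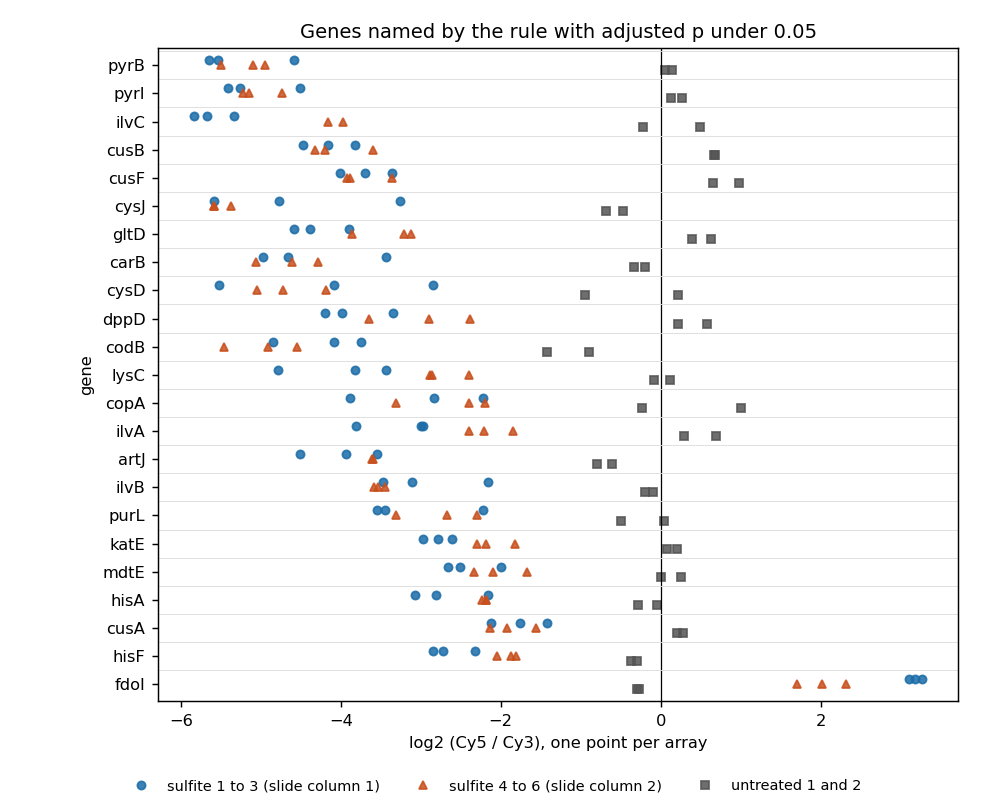
log2 ratio of Cy5 over Cy3 (horizontal axis) for the 23 called genes named by the fixed rule (vertical axis), one point per array: circles sulfite 1 to 3, triangles sulfite 4 to 6, squares untreated 1 and 2. Every sulfite point of the first 22 genes lies left of both squares, and fdoI lies right of them.

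Some whole lists lay apart from other genes on the sulfite arrays by camera at the preset correlation, but none with an estimated correlation. Branched-chain amino acid, cysteine, histidine, arginine and nucleotide synthesis and copper and zinc homeostasis lay lower in Cy5. Isc iron-sulfur assembly lay higher. Camera called 18 of 37 lists, 15 lower and 3 higher in Cy5. With an estimated correlation, where none was called, the lowest adjusted p was 0.193. The alternative fry, which does not compare a list with other genes, called the 7 lists just named. By the labels, lists lower in Cy5 were higher after sulfite; with the channels exchanged, they were lower. The slide column as a block kept all 18 calls and added aromatic amino acids (adjusted p = 0.0136), the pentose phosphate pathway (0.0161) and aerobic respiration (0.0361), and 9 lists were called on the same side within both columns. With an estimated correlation no list was called within a column either, and the lowest adjusted p was 0.223 in column 1 and 0.601 in column 2.

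The branched-chain list had a median difference of -3.01 (adjusted p = 8.67e-15), the cysteine list -2.44 (1.11e-09), the histidine list -2.31 (1.56e-11), the purine and pyrimidine list -1.03 (1.65e-08) and the copper and zinc list -0.83 (2.3e-07). Each of these had an adjusted p = 0.193 with an estimated correlation. The arginine list had a median of -1.52 (adjusted p = 1.88e-07, and 0.274 with an estimated correlation). The glycolysis and glucose uptake list had -1.11 (adjusted p = 1.88e-07, and 0.239 with an estimated correlation), with none of 14 members called and 5 when adjusted over the list alone. The acid resistance list had -2.33 (adjusted p = 1.03e-05, and 0.365 with an estimated correlation). These 8 lists were called lower within both columns, but with median centring glycolysis was not called within column 1 (median -0.35, adjusted p = 0.176). The purine and pyrimidine median was -0.54 without untreated 1 and -1.77 without untreated 2, and the copper and zinc median -0.54 without sulfite 4, all still called. The Isc list, whose proteins build iron-sulfur clusters, had 1.69 (adjusted p = 3.64e-07, and 0.193 with an estimated correlation), none of 8 members called and 4 higher when adjusted over the list alone. It was called within both columns too, and its medians were -0.61 and -1.00 on the untreated arrays and 0.07 to 1.70 on the sulfite arrays.

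The other called lists were not called within both columns. Iron acquisition had a median of -1.46 (adjusted p = 6.02e-10, and 0.365 with an estimated correlation), none of 35 members called and 8 when adjusted over the list alone. Its median was -1.23 on untreated 1 and -0.23 on untreated 2, and its difference was -0.70 within column 1 and -1.95 within column 2; without untreated 2 it was -0.66 and still called. RpoS general stress had -1.06 (adjusted p = 0.00549), with 1 member called when adjusted over the list alone. The tricarboxylic acid cycle had -0.98 (0.0122), Suf iron-sulfur assembly -0.78 (0.0442) and ATP synthase -0.61 (0.0487). Anaerobic respiration had -0.45 (0.013), methionine synthesis -0.29 (0.0442) and ribosomal proteins 0.21 (0.000795). Each of these 7 had an adjusted p = 0.637 with an estimated correlation. Sulfane sulfur and sulfide handling had 0.28 (adjusted p = 0.0279, and 0.193 with an estimated correlation). Apart from katE of the RpoS list, no member of these lists was called over all genes. Leaving aside iron acquisition and RpoS, only 1 gene of methionine synthesis passed when adjusted over the list alone. Leaving out 1 array ended each of these calls except that of iron acquisition. The methionine median was 0.23 without untreated 1 and not called, -0.98 without untreated 2, -0.61 without sulfite 1 and -0.55 without sulfite 5, and the call also ended without sulfite 2 (-0.27), 3 (-0.26), 4 (-0.20) or 6 (-0.14). The Suf median was -0.18 without untreated 2 and not called, and -1.35 without untreated 1; the call ended without sulfite 1 (-0.58), 2 (-0.67), 3 (-0.80) or 5 (-0.72). The ribosomal median was 0.00 without sulfite 1 and not called, 0.02 without untreated 2, 0.34 without untreated 1 and 0.34 without sulfite 6. The RpoS call ended without sulfite 1 (-0.56) or 3 (-0.76), and its median was -1.60 without sulfite 6. The ATP synthase call ended without untreated 1 (-0.37) or sulfite 4 (-0.45), 5 (-0.49) or 6 (-0.51). The anaerobic call ended without untreated 2 (-0.32) or sulfite 1 (-0.34) or 5 (-0.33), the tricarboxylic acid cycle call without untreated 1 (-1.00), and the sulfane sulfur call without sulfite 1 (0.51) or untreated 2 (0.26). The calls for methionine synthesis, Suf assembly and ATP synthase were also lost with median centring, and that for ribosomal proteins with the scanner's own normalization.

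Without the block, no shift was called for the other 19 lists, and none of their members was called over all genes. Median differences were -0.10 for molybdenum cofactor synthesis, -0.38 for the pentose phosphate pathway and -0.52 for aromatic amino acids, with 5, 1 and 1 members lower when adjusted over the list alone. They were -0.03 for taurine and sulfonate use, -0.16 for thiol and glutathione redox, -0.10 for SoxRS, -0.10 for heat shock, -0.28 for envelope stress and -0.35 for the electrophile and chlorine response. They were -1.15 for the 4 ribosome hibernation genes, -0.70 for aerobic respiration, 0.17 for phage shock, 0.12 for SOS and 0.20 for osmoprotection. In 4 lists the median, the mean and camera's direction differed in sign: methionine sulfoxide repair (median 0.26, mean -0.07, camera lower), OxyR (0.03, -0.25, lower), multidrug efflux (-0.08, 0.01, higher) and flagella (0.01, -0.14, higher). Curli and biofilm had a median of 0.08. The flagella median turned negative with the scanner's own log ratio or processed signals, and the curli median with median centring. The scanner's own log ratio called SOS (0.30, adjusted p = 0.0425) and aromatic amino acids (-0.58, 0.0422), and so did the processed signals (0.0456 and 0.0420). With the normalization used here and no block, adjusted p-values of these 19 lists ran from 0.0584 to 0.89, and from 0.365 to 0.916 with an estimated correlation.

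**Figure D3:**
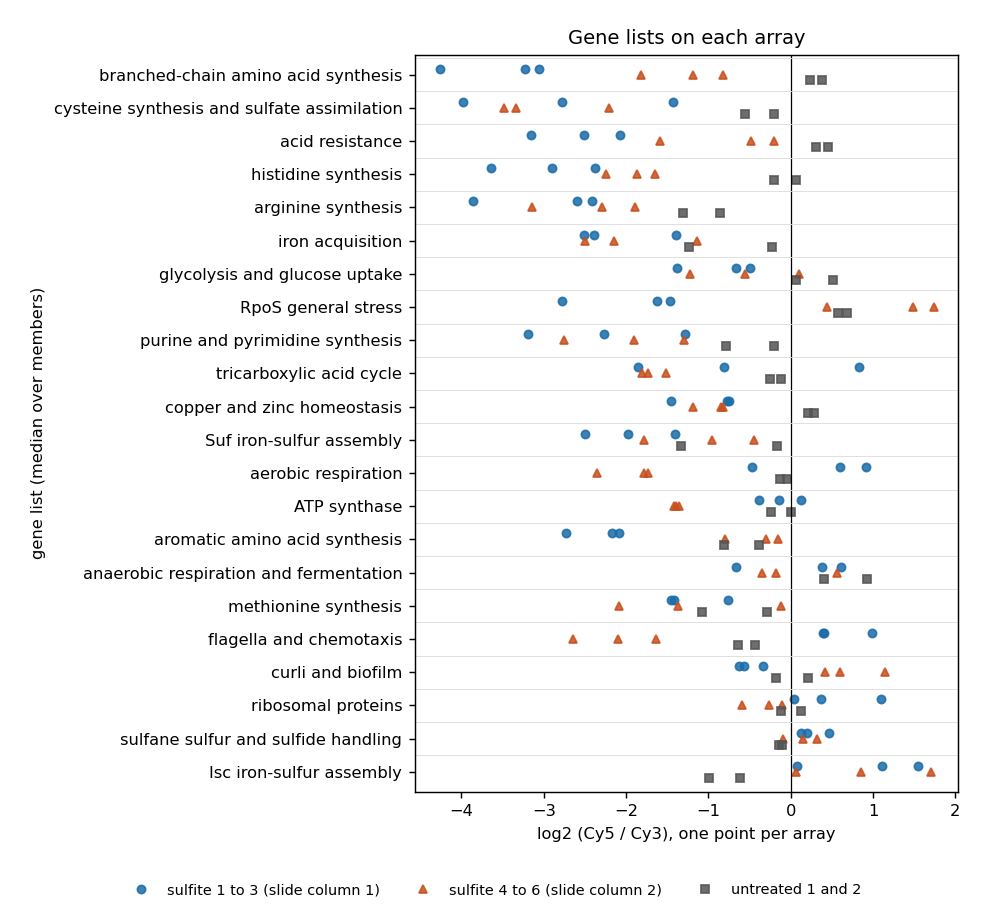
Median log2 ratio of Cy5 over Cy3 over the measured members (horizontal axis) of 22 gene lists (vertical axis), those called by camera or differing between slide columns, one point per array: circles sulfite 1 to 3, triangles sulfite 4 to 6, squares untreated 1 and 2. The median of the branched-chain genes lies left of both squares on every sulfite array. The median of the flagella genes lies at 0.39 to 0.99 on sulfite 1 to 3 and at -2.65 to -1.63 on sulfite 4 to 6.

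The sulfite arrays of slide columns 1 and 2 differed from each other, which the labels do not account for. As a list, flagella and chemotaxis genes lay higher in Cy5 within column 1 and lower within column 2, and the RpoS general stress list lay lower within column 1 only. Of 44 flagella genes, none was called within column 1 and 4 were lower within column 2, and fliC was at -1.60 and -0.24 on sulfite 1 and 2. Of 23 RpoS genes, 4 were lower within column 1 and 1 was lower within column 2. For flagella the median difference was 0.87 within column 1 (camera adjusted p = 1.77e-10, or 0.442 with an estimated correlation) and -1.24 within column 2 (2.9e-08, or 0.648), and the test of the difference between columns gave an adjusted p = 1.18e-16, or 0.596 with an estimated correlation. For the RpoS list it was -2.76 within column 1 (adjusted p = 1.39e-12, or 0.436 with an estimated correlation) and 0.46 within column 2, where it was not called (adjusted p = 0.149), with an adjusted p = 5.01e-10 for the difference, or 0.637 with an estimated correlation. Aerobic respiration had 0.48 and -1.72, with an adjusted p = 6.48e-06 for the difference, or 0.728 with an estimated correlation. Aromatic amino acid synthesis had -1.49 and 0.16, with an adjusted p = 3.4e-09 for the difference, or 0.247 with an estimated correlation. Lower in both columns but to different extents were the branched-chain list (-3.54 and -1.53, adjusted p = 1.89e-08 for the difference, or 0.596 with an estimated correlation) and the acid resistance list (-2.70 and -1.41, adjusted p = 0.00111, or 0.728 with an estimated correlation). Iron acquisition (adjusted p = 1.39e-06, or 0.728 with an estimated correlation), ribosomal proteins (0.00111, or 0.826), ATP synthase (0.00111, or 0.596) and curli and biofilm (0.0326, or 0.596) also differed. In all, 10 of 37 lists and 16 of 3861 genes differed between the columns (camera and limma). The count of 16 understates the gap, as this test recovered 6% of simulated log2 changes of 2. Against a ratio of 0, 142 genes were called lower in column 1 and higher in column 2, and 46 the reverse, 188 in all. On the same side in both columns, 243 were lower and 35 higher. Single members could depart from their list: leuA of the branched-chain list differed by -6.04 within column 1 and 0.03 within column 2. The list values within columns depended on the normalization. With median centring in place of loess, ribosomal proteins were at 1.47 within column 1 and -0.74 within column 2, ATP synthase at 0.80 and -1.65 and aerobic respiration at 1.25 and -2.37, all 6 called. Heat shock, the tricarboxylic acid cycle and glycolysis then differed between columns too, which made 13 lists. With the scanner's own log ratio, the acid resistance list was at -4.12 and -1.61. The 10 lists above differed between columns in each of these settings. Log2 ratios of 2 sulfite arrays from different columns correlated across genes at r = -0.03 to 0.35. By the labels, the flagella list as a whole lay lower after sulfite in column 1 and higher in column 2; with the channels exchanged, the reverse holds.

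On the 2 arrays with untreated RNA in both channels, no gene was called as different from 0. The limma test passed 0 of 3869 genes at an adjusted p under 0.05, and 205 at an unadjusted p under 0.05. It uses the spread within both groups and ignores the slide column, so a gap between the columns widens that spread. The 0 calls therefore do not exclude ratios that agree on both arrays: groL was at 2.38 and 2.05 on untreated 1 and 2. Such ratios are carried into the differences between sulfite and untreated arrays, which for groL was -2.55 and did not pass. Whether they come from the dyes or from unlike untreated extracts was not tested. Some genes named above, chosen after their values were seen, had ratios away from 0 there that did not pass this test. codB averaged -1.16 ± 0.37, gapA 0.95 ± 0.20, cusF 0.82 ± 0.23 and cusB 0.67 ± 0.01 (SD, n = 2). Untreated 1 and untreated 2 correlated at r = 0.52 across genes. Without subtracting these arrays, 470 genes of the sulfite arrays were lower and 145 higher in Cy5 against a ratio of 0.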

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

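All tests of explanations in this part were chosen after the results were seen, and so were the models within slide columns; the search for outlying arrays followed a fixed rule.

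A few named genes had 1 sulfite array far from the others, by a gap test over the 6 arrays that chance alone trips in about 1 of 20 cases; 35 genes and the 18 called lists were searched. Sulfite 3 stood apart in 3 of the 4 genes found. ibpA had a log2 ratio of 5.47 there, against -0.27 to 0.39 on the other 5 arrays. cysI was at -1.65 on sulfite 3, against -5.09 to -4.06, and cysJ was at -3.26, against -5.59 to -4.77. Sulfite 3 was weaker in more of the cysteine list, whose median was -1.44 there and -3.99 to -2.20 on the other 5 arrays. Chosen after their values were seen, cysH, cysC, cysA and cysW were at -1.04, -1.79, -1.83 and -1.95. Their other arrays lay at -5.30 to -3.49. cysP (-3.40) and tcyP (-2.72) were not set apart there. ilvB was at -2.16 on sulfite 2, against -3.58 to -3.12.

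The first pattern is the likeness of Cy3 to untreated RNA on the sulfite arrays. Cy3 was closer than Cy5 to the untreated Cy5 channels on 6 of 6 arrays, as it would be if the channels of these arrays were exchanged in the labels, and it was also 6 of 6 without background subtraction and with median centring. A dye effect that makes all Cy3 channels alike is argued against, since the match holds across dyes: the mean r was higher for Cy3 than for Cy5 by 0.108, with an SD of 0.017 over the arrays. It stays open whether the labels are right and the Cy5 RNA came from untreated cultures unlike those of the untreated arrays (mean r 0.854), because the labels name no second measurement of those cultures. That reading needs sulfite RNA in Cy3 to match untreated Cy5 channels at r = 0.937 to 0.990. The 2 channels of untreated 1 and of untreated 2 matched each other at 0.974 and 0.952. It also needs untreated RNA in Cy5 to correlate at only 0.755 to 0.776 between slide columns. An exchange of the channel labels is a candidate explanation, and it would turn every direction given here without changing a size or a count.

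The second pattern is the gap between the sulfite arrays of slide columns 1 and 2. Against a ratio of 0, 188 genes were called on opposite sides in the 2 columns. The limma test of the difference between columns, which has little power for smaller changes, called 16 genes. They were tyrA and aroF of aromatic amino acid synthesis (differences of -1.15 and -1.37 within column 1 and 6.90 and 7.38 within column 2), leuA, leuB, thiC, panD, osmY, phoH, yceK, yeiH and yhjE, all higher in Cy5 in column 2 than in column 1, and sdaB, sdaC, flgC, flgE and fliL, which lay the other way. An effect of the slide column on the arrays would lower the likeness of both channels, but the lowest r between Cy3 channels across columns exceeded the highest between Cy5 channels by 0.161, so the gap lies in Cy5. Dyes swapped on the arrays of 1 column would turn the ratios around, whereas the mean log2 ratios of the columns correlated at r = 0.211 across genes. A condition that the labels do not state may separate sulfite 1 to 3 from sulfite 4 to 6; no biological explanation was tested.

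Other choices of the control pair do not exclude chance for the count of called genes. Of the 28 ways to take 2 of the 8 arrays as the control pair, 2, the real pair included, gave at least its 35 genes, and the highest other count was 48, with sulfite 2 and sulfite 3 as the pair. Those arrays lie in the same slide column, but the other 5 pairs of sulfite arrays of 1 column gave 0 genes. With the column as a block the real pair gave 53 genes (50 lower and 3 higher in Cy5) and sulfite 2 and 3 gave 2. But sulfite 1 and sulfite 5, 1 array of each column, gave 112. Again 2 of 28 pairs, the real one included, gave as many as the real pair. Every other pair leaves untreated and sulfite arrays in the same group, and the sulfite arrays themselves differ between slide columns. The counts of the other pairs thus do not measure chance in either direction. The Cy3 channels of sulfite 1 and 5 correlated at r = 0.987, but the cause of their count was not tested.

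Probes that the comparisons of K-12 genes did not use also carried a signal. Of 2570 tested probes for other E. coli strains and 268 custom probes, 21 in all had a ratio that differed between sulfite and untreated arrays (limma, adjusted p under 0.05), 20 lower and 1 higher in Cy5. Of 20 called probes for other strains, 8 bear the same gene name as a called K-12 gene. The match was by gene name alone. Probes named by another scheme, such as ECs0943, were not matched, so the other called probes are not shown to measure different genes.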

How the results depend on the processing

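The models within slide columns were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of 871 comparisons of named genes with an alternative, 743 stayed on the same side of the threshold, 97 lost the call, 29 gained one and 2 reversed with a call. The 743 include 13 in which ibpA, recA, rpoS or soxS changed sign without a call. For the called lists, 392 of 456 kept camera's direction and the call, 55 lost the call and 9 reversed. All 35 called genes had at least a 2-fold change, and the brightest probe per gene, which concerns 24 loci, kept all calls. Aquantile normalization leaves log ratios as they are, so its 35 gene and 18 list comparisons were kept by construction. Spots near the background limit the ratios of dim genes, and the number of arrays limits the rest. Where the cause of a change is not named, the cause was not tested.

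The number of genes lower in Cy5 (34) was 21 with the scanner's own log ratio, 470 for the sulfite arrays against 0, 81 for the mean of both column effects, 67 within column 1, 618 for column 1 against 0 and 747 for column 2 against 0. Leaving out 1 array gave 4 to 35. The number higher in Cy5 (1) was 2 without background subtraction, 2 with the processed signals, 2 without the filter, 145 against 0, 3 with the column block, 16 for the mean of both column effects, 18 within column 1, 14 within column 2, 177 for column 1 against 0 and 519 for column 2 against 0. Leaving out 1 array gave 0 to 1. In the authors' deposited table, which holds 575 K-12 genes, 0 were called in either direction (limma; 0 shared with the 35), and 2 of 14 testable lists were called. The number of lists called (18) was 0 with an estimated correlation and 7 with fry, and 13 to 19 when 1 array was left out. The count for the untreated arrays against 0 was also 0 with median centring, without background subtraction and with 1 sulfite array left out. There 163 to 401 genes had an unadjusted p under 0.05 (limma). All these fits ignore the slide column, and this count was not made with the column in the model.

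The replicate block gave 610 genes lower and 362 higher in Cy5 among 3635 with an estimate, and 31 of the 34 were among the 610. It has 1 residual degree of freedom and rests on the numbers 1 and 2, which both groups share. Deviations from the group means correlated at 0.51 for the arrays numbered 1 and at 0.16 for those numbered 2; as 2 untreated arrays deviate as mirror images and only 2 pairs exist, the number is not taken as a pairing.

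Reversed values were soxS at -0.60 in column 1 against 0, and rpoS at 2.95 in column 2 against 0. The RpoS list had a median of 0.46 within column 2 and 1.30 in column 2 against 0. Ribosomal proteins, by camera's direction, had 0.17 within column 2 (-0.74 and called with median centring) and -0.34 in column 2 against 0. ATP synthase, where camera's direction turned and the median did not, had -0.14 with the replicate block and -0.12 within column 1; with median centring its column 1 median was 0.80 and called. Anaerobic respiration had 0.23 against 0, 0.10 in column 1 against 0 and 0.13 in column 2 against 0. The methionine median changed sign while camera's direction did not, at 0.15 within column 2 and 0.23 without untreated 1, and so did the ribosomal median in the authors' table (-0.17).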

Other observations

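The genes and channels in the next paragraphs were chosen after their values were seen.

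Beyond the genes named by rule, 12 called genes were lower in Cy5 on the sulfite arrays. They include neighbours of the named genes in the same pathways. gdhA, glutamate dehydrogenase, was 8.55-fold lower, next to gltD in glutamate synthesis. livF and livG of the branched-chain amino acid transporter were 9.88-fold and 9.10-fold lower, and thrB and thrC of threonine synthesis 9.42-fold and 7.76-fold. bioA, bioC and bioD of biotin synthesis were 3.35-fold, 5.42-fold and 3.39-fold lower. codA, cytosine deaminase, was 5.91-fold lower, dppF 4.04-fold (Cy5 above background on 4 of 6 sulfite arrays), pntB of the membrane transhydrogenase 6.24-fold and ugpC 2.47-fold. By the labels they were higher after sulfite; with the channels exchanged, lower. For livF, livG and bioC, Cy5 was above background on 5 of 6 sulfite arrays.

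The small heat shock protein genes ibpA and ibpB set sulfite 3 apart from the other sulfite arrays. ibpB had a log2 ratio of 5.90 there and between -0.26 and 0.26 on the other 5 sulfite arrays, as its neighbour ibpA did at 5.47. The median of the heat shock list was 1.60 on sulfite 3, 0.42 on sulfite 2 and -0.30 to -0.14 on the other 4. Other chaperone genes were also high on sulfite 2: groL was at 1.47 there and 1.63 on sulfite 3, groS at 1.17 and 1.23, and htpG at 1.26 and 1.82. On the untreated arrays groL was at 2.38 and 2.05 and htpG at 1.63 and 1.51. The limma test against 0 called 0 genes on those arrays (205 at an unadjusted p under 0.05), but it ignores the slide column. Its spread for groL takes in -0.30 to 1.63 on sulfite 1 to 3 and -2.44 to -0.48 on sulfite 4 to 6. The test could therefore miss such ratios.

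Some Cy3 channels lay close to a channel of another array. The nearest channel on another array was Cy3 of sulfite 5 for Cy3 of sulfite 1 (r = 0.987), Cy3 of sulfite 6 for sulfite 2 (r = 0.991) and Cy3 of sulfite 4 for sulfite 3 (r = 0.988), and the highest match was Cy3 of sulfite 6 with Cy3 of untreated 2 (r = 0.994). Across dyes, Cy5 of untreated 2 was nearest to Cy3 of sulfite 5 (r = 0.990) and Cy5 of untreated 1 nearest to Cy3 of sulfite 3 (r = 0.981). Whether RNA extracts were shared between arrays was not tested. The 6 sulfite arrays are therefore not known to hold 6 separate extracts in Cy3, whichever RNA that channel carries. The SDs and p-values count arrays.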
